A study of Mus musculus with 8 samples.

How the data were processed

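RNA from the tibial plateau of the knee, cartilage dissected in 1 piece with the bone beneath it, was measured on 8 microarrays, 1 per sample. Per the labels, 4 samples came from wild-type C57BL/6 mice and 4 from Anp32a knockout mice, all aged 8 weeks. No strain is given for the knockout mice in the sources used here. Tissue was taken straight after death, RNA was extracted with Trizol, and 2 µg per sample was amplified to biotin-labelled antisense cRNA by the Affymetrix protocol, per the labels' protocols. The array design and the software versions are not given in the sources used here.

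The deposited values are log2 expression values per probe set made with RMA (robust multi-array average), per the submitters' processing notes. RMA corrects background, brings all arrays to 1 distribution by quantile normalization and summarises the probes of a probe set. Both deposited tables hold the same log2 values for 45037 probe sets. The table with statistics also holds, per the file headers, gene symbols, detection calls (present, marginal or absent, for each probe set and array), and the authors' log2 fold changes, p-values and adjusted p-values. Its last 64 rows hold calls without an identifier and were not used. No gene symbol is given for 6889 probe sets, and 62 carry a date in its place, as spreadsheets make of some symbols; both kinds were left unnamed. RMA's quantile step can hide a shift of most genes in 1 direction. The log2 fold changes and p-values of the authors' deposited table were recomputed per probe set by an unpaired limma fit, and log10 p differed by at most 0.00114.

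The number of arrays, 4 per group, limits the precision. Present calls covered 57.6% to 60.1% of the probe sets of an array. Per the file headers each array is 1 numbered mouse. The p-values measure only the spread between these samples. Wild-type and knockout arrays share the numbers 1 to 4, with no stated pairing, so the comparison was unpaired.

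Each gene was represented by the probe set with the highest mean over the 8 arrays, which gave 20667 genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. No probe set was filtered out and no further normalization was applied. Because probe sets of a gene can part, all 45037 probe sets were also tested one by one. A probe set called absent on every array of a group has only a bound there. Its fold is given as "at least", from the mean of the bright group against the mean of, per array, the higher of its own value and the lowest value called present on that array. For every named probe set so treated its own values were the higher, so the fold given equals the measured fold.

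Gene lists, 38 in number, were fixed before the data were examined. They cover chondrocyte and bone cells, marrow cells, muscle, fat, vessel, tendon and synovium markers, DNA damage, oxidative stress and other pathways, and 635 of their 661 entries were measured. They were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, fry, and an exact permutation test of the list mean per array over all 70 ways to part 8 arrays into 4 and 4 served as checks. With 4 arrays against 4, the smallest two-sided exact p is 0.0286.

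The files name no genome build. Gene order and chromosome were taken from the GRCm38.p6 annotation, which placed 18500 of the 20667 genes and 35618 probe sets, and no coordinates from it are given. Genes within 10 Mb of Anp32a were compared with all other placed genes by Fisher's exact test on the share at unadjusted p under 0.05.

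The rule for the genes named was fixed before the data were examined. It takes Anp32a and Atm, and in each direction the 10 called genes of largest change with non-overlapping groups. Where fewer were called, genes of smallest p that did not pass fill the place. It adds up to 4 members (2 were taken from most lists and 4 from the heat shock list, a choice made after the values were seen) of smallest p from each shifted list and from the antioxidant enzyme, NRF2 target, DNA damage and chondrocyte lists, and members of highest level from cell type lists. Gene models without a symbol of their own are counted but not named. Genes named outside this rule are said to be so.

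The gene test was tested on simulated data with the levels and spread of these arrays, over 20667 genes. It recovered 30 of 50 genes changed by 0.5 log2, 43 of 50 changed by 0.75, 48 of 50 changed by 1 and 50 of 50 changed by 2, with 10 false calls among 181. Camera recovered 3 of 3 shifted lists with 1 false call over 38 lists. Noise was drawn independently for each gene, so neither simulation shows how the tests behave where genes move together. In the real lists the estimated correlation between members reached 0.899.

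Alternatives fixed beforehand were a replicate block, quantile normalization or median centring of the deposited values, genes above the median level only, the mean of a gene's probe sets, all probe sets one by one, trended and robust eBayes, array weights, an ordinary per-gene test, adjusted p under 0.1, each array left out in turn, muscle or erythroid list means as covariates, and other list tests and window widths. Further alternatives were added after the data were seen.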

Results

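Gene expression was compared between the knee tibial plateau of 4 Anp32a knockout mice and 4 wild-type mice at 8 weeks of age. The comparison asks which genes differ in joint tissue that lacks Anp32a, which encodes an acidic leucine-rich nuclear phosphoprotein. The dissected piece held articular cartilage and the bone beneath it, a bone that carries marrow. All values are log2 RMA values, ± SD with n = 4 per group, and fold changes are knockout over wild type. Arrays of the same genotype correlated at r = 0.9906 to 0.9971 across probe sets, which are not independent replicates. The first principal component held 52.8% of the variance and did not part the genotypes: knockout 2 and knockout 3 lay at 44.0 and 44.5, knockout 1 at 11.3, and knockout 4 at -11.9, among wild types at -9.88 to -36.8.

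The targeted gene was lost on all 4 knockout arrays by 1 of its 3 probe sets. This probe set of Anp32a read 9.88 ± 0.08 in wild type, present on 4 of 4 arrays, and 4.60 ± 0.49 in knockout, absent on 4 of 4 (at least 38.9-fold lower, limma adjusted p = 5.9e-06 over all probe sets). The other 2 probe sets stayed present on all 8 arrays. The brightest read 10.40 ± 0.04 and 9.89 ± 0.12 (log2 fold change -0.51, limma adjusted p = 0.0555), and the remaining one gave -0.45 (limma adjusted p = 0.0641). Which part of the gene was deleted, and where each probe set lies, is not given in the sources used here, and a probe set outside the deleted part checks nothing. In the gene-level test Anp32a is represented by its brightest probe set and did not pass (limma adjusted p = 0.0713). Knockout 4, which lay among the wild types on the first component, read 5.04 for the lost probe set, against 4.98, 4.05 and 4.33 on the other knockout arrays. Without knockout 4 the brightest probe set passed at gene level (-0.51, limma adjusted p = 0.0272).

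**Figure D1:**
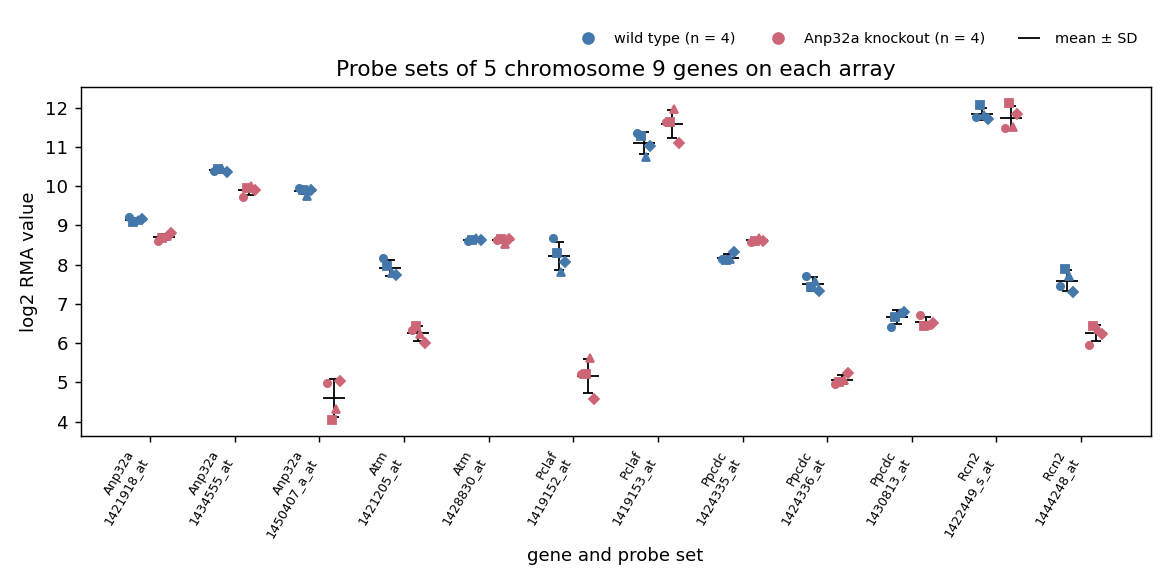
Log2 RMA value of each probe set of Anp32a, Atm, Pclaf, Ppcdc and Rcn2 on each of the 8 arrays, with gene and probe set identifier along the horizontal axis; points are arrays and bars are mean ± SD (n = 4 per genotype). The third Anp32a probe set from the left fell from 9.88 to 4.60 and the left Atm probe set from 7.92 to 6.25, while the right Atm probe set read 8.64 and 8.62.

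Few single genes passed the threshold. Immunoglobulin heavy chain Ighg, made by plasma cells, was higher in the knockout (9.72 ± 0.70 against 6.96 ± 0.38, 6.78-fold, limma adjusted p = 0.0246), as was Mid1, an E3 ubiquitin ligase gene on the X chromosome (8.30 ± 0.34 against 6.82 ± 0.09, 2.78-fold, limma adjusted p = 0.0161); the other 2 Mid1 probe sets were absent on all arrays. Cadm1, a cell adhesion molecule, rose 1.72-fold and Ppp2r1b, a scaffold subunit of protein phosphatase 2A, rose 1.69-fold (limma adjusted p = 0.0378 and 0.0171). Plet1os fell at least 5.23-fold, from 6.24 ± 0.49 to 3.85 ± 0.07 with an absent call on all knockout arrays (limma adjusted p = 0.00678). Nxpe4 fell by 1.01, the kinase gene Dapk2 by 0.93 and the heat shock protein gene Hsph1 by 0.71 on the log2 scale (limma adjusted p = 0.0218, 0.013 and 0.0378).

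In all, 11 of 20667 genes passed limma with Benjamini-Hochberg adjustment, 6 higher and 5 lower in the knockout, among them 3 gene models not named here. At an unadjusted p under 0.05 the count was 4008, of which 2095 were higher and 1913 lower. The groups did not overlap for any of the named genes above, and in all for 2072 genes (10%), where chance gives 2.86% on average over splits. Genes move together, so the share under a single split can lie far from that average. The share in other splits was not counted, so the 10% does not exclude chance. Genes that came next and did not pass were, on the higher side, Jchain (log2 fold change 1.70), a part of secreted immunoglobulins, Lrrc49 (1.12), Gdpd2 (0.70), Tkt (0.46), Ccdc9 (0.45) and Ppcdc (0.45). On the lower side they were the bicarbonate transporter gene Slc4a4 (-0.88), Eya4 (-0.83), the kinase gene Map2k6 (-0.52), Mtfmt (-0.46) and Bcl9l (-0.41), with limma adjusted p from 0.0807 to 0.145 over both sides. Without knockout 4 each of these 11 passed (limma adjusted p = 0.0132 to 0.0297), Mtfmt also after quantile normalization (0.0482) and Eya4 with array weights (0.0452). Among the 11, Ppcdc, Lrrc49, Mtfmt and Bcl9l lie within 20 Mb of Anp32a on chromosome 9, as do 385 of all 18500 placed genes.

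The count depended on single arrays. Leaving out knockout 4 gave 1786 genes (944 higher, 842 lower), which included all 11, and 5409 at an unadjusted p under 0.05. Leaving out knockout 1, 2 or 3 gave 4, 6 and 4 genes, and leaving out wild type 1, 2, 3 or 4 gave 3, 2, 1 and 3. Of the 11 genes, 1 to 6 passed in those 7 fits. Plet1os was lost without wild type 3 (limma adjusted p = 0.0522), Dapk2 without knockout 1 or wild type 2, 3 or 4 (up to 0.0657), Mid1 without knockout 3 or any wild type (up to 0.0932) and Nxpe4 without knockout 1, knockout 3 or any wild type (up to 0.114). Ighg, Cadm1, Ppp2r1b and Hsph1 were lost without any 1 array except knockout 4 (limma adjusted p = 0.0559 to 0.163). Without knockout 4, 16 of the 25 cell cycle genes and 4 of the 17 erythroid genes were called higher, and 10 of the 25 muscle genes and 2 of the 30 respiratory chain genes lower, so that many members given below with values only were called in that fit. With knockout 2 and knockout 3 left out together, chosen after the data were seen because they were lowest in muscle genes, 1 gene passed, none of the 8 named above.

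Calls of the 8 named genes also depended on the settings. With the muscle list's mean as a covariate Ighg read 2.18, Mid1 1.21, Cadm1 0.59, Ppp2r1b 0.70, Plet1os -2.22, Nxpe4 -1.13, Dapk2 -0.93 and Hsph1 -0.62, and none passed (limma adjusted p = 0.132 to 0.44). With the erythroid list's mean Ighg, Mid1, Cadm1, Ppp2r1b and Hsph1 read 2.39, 1.57, 0.70, 0.67 and -0.69 and did not pass (limma adjusted p = 0.155, 0.0525, 0.23, 0.117 and 0.23), so the calls were lost with log2 fold changes within 0.4 of those of the plain comparison. The numbers 1 to 4 of the array titles, for which no pairing is stated, were also fitted as a block. In that fit Ighg, Cadm1, Ppp2r1b, Nxpe4, Dapk2 and Hsph1 kept their fold changes and did not pass (limma adjusted p = 0.0808, 0.152, 0.0648, 0.0808, 0.0808 and 0.152). With the mean of all probe sets of a gene Ighg and Cadm1 did not pass (limma adjusted p = 0.0796 and 0.11), and Mid1 passed at 0.54, its absent probe sets included. Among probe sets, the other 1 of Ighg (limma adjusted p = 0.097) and the other 3 of Cadm1 (0.0706, 0.0528 and 0.145) did not pass. Hsph1 was lost without the genes within 20 Mb of Anp32a (limma adjusted p = 0.0737), a setting chosen after the data were seen.

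The probe-set test added genes near Anp32a on chromosome 9. In it, 24 of 45037 probe sets passed (9 higher, 15 lower; 8225 at an unadjusted p under 0.05), of which 6 have no symbol and 18 belong to 17 genes. Of the 14 that could be placed, 11 belong to chromosome 9 genes within 20 Mb of Anp32a: Anp32a itself, Ppcdc, Pclaf, Atm, Rcn2, Peak1, Dapk2, Plet1os, Nxpe4, Cadm1 and Ppp2r1b. This was 11 of 749 probe sets in that window against 3 of 34869 placed elsewhere (Fisher's exact p = 1.1e-16, two-sided, and 4.1e-15 without Anp32a; the window of 20 Mb was looked at for called probe sets after the data were seen). Within 10 Mb it was 7 of 399 against 7 of 35219 (Fisher's exact p = 6.7e-11, two-sided). At gene level it was 5 of 385 against 2 of 18115 within 20 Mb (Fisher's exact p = 7.7e-08, two-sided), but 1 of 197 against 6 of 18303 within 10 Mb, which did not pass (Fisher's exact p = 0.0722, two-sided). Leaving out knockout 4 gave 3579 probe sets, and leaving out wild type 1, 2, 3 or 4 gave 14, 9, 10 and 14; without knockout 1, 2 or 3 the counts were 24, 18 and 17.

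**Figure D2:**
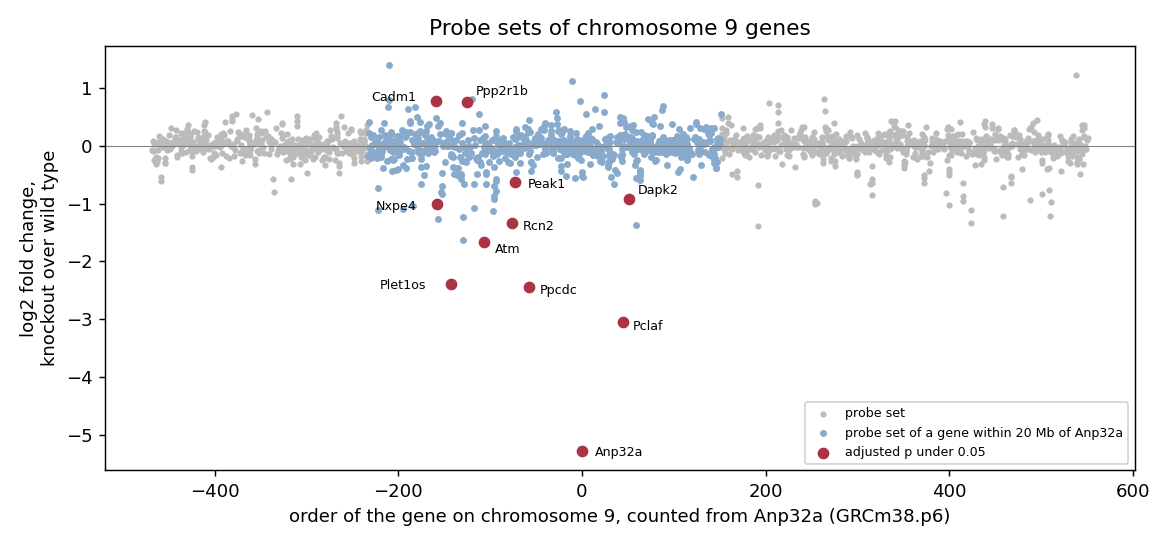
Log2 fold change, knockout over wild type, of each probe set of a placed chromosome 9 gene, against the order of the genes counted from Anp32a in GRCm38.p6; blue points lie within 20 Mb of Anp32a and large points passed an adjusted p of 0.05. All 11 called probe sets lie within 20 Mb, from Cadm1 and Nxpe4 on one side to Dapk2 on the other.

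Atm, the gene of the ATM kinase, gave different readings from its 2 probe sets. The dimmer fell from 7.92 ± 0.20 to 6.25 ± 0.19, 3.17-fold and lower on 4 of 4 knockout arrays (limma adjusted p = 0.000938 over all probe sets). The brighter, which represents the gene, read 8.64 ± 0.03 in wild type and 8.62 ± 0.06 in knockout (log2 fold change -0.02, limma adjusted p = 0.926). The mean of the 2 read -0.84 at gene level and passed (limma adjusted p = 0.003), as did that of the Ppcdc probe sets given below (-0.71, limma adjusted p = 0.00118). Both Atm probe sets were present on all 8 arrays. Other neighbours of Anp32a parted in the same way. Pclaf, a PCNA-binding factor, fell by 3.05 on the log2 scale in its dimmer probe set while the brighter read 0.48 higher without passing (limma adjusted p = 0.000991 and 0.219). Ppcdc, an enzyme of coenzyme A synthesis, fell at least 5.44-fold in 1 probe set and read 0.45 higher in its brightest (limma adjusted p = 5.9e-06 and 0.0706), while Rcn2 fell at least 2.53-fold in its dimmer probe set and read -0.11 in the brighter (limma adjusted p = 0.0122 and 0.757). The Rcn2 call was lost without wild type 3 (limma adjusted p = 0.0667), with the erythroid covariate (0.114) and without knockout 2 and 3 (0.0582), and the calls of Anp32a, Atm, Pclaf and Ppcdc passed without any 1 array. The authors' deposited table gives the same fold changes for these probe sets, with adjusted p = 0.00094 for the dimmer Atm probe set. The deposited files do not say which transcript region each probe set reads.

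Genes within 10 Mb of Anp32a, whose behaviour bears on what a knockout allele carries with it, more often had an unadjusted p under 0.05 than other genes: 54 of 197 (27.4%) against 3736 of 18303 (20.4%; odds ratio 1.47, 95% interval 1.05 to 2.03, Fisher's exact p = 0.0206, two-sided). The 54 were 27 higher and 27 lower, and camera found no common shift (camera adjusted p = 0.864, equal to its unadjusted p since this set is alone in its family). Within 5 Mb the share was 32.5%, from 5 to 10 Mb 20%, from 10 to 20 Mb 30.3%, and from 20 to 30 Mb 18.6%. The result passed 0.05 no longer without knockout 1 (p = 0.057), knockout 2 (p = 0.0938) or wild type 3 (p = 0.0544), and Fisher's test takes genes as independent, which neighbours are not.

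Skeletal muscle genes were the list with the lowest mean in the knockout. Their mean log2 fold change was -0.66 over 25 genes, all below 0, and 18 passed adjusted over the list alone (0 over all genes). Mybpc2 read 12.60 ± 0.78 in knockout (log2 fold change -1.04) and Myoz1 -1.08, while the most abundant members, Tnnc2 and Myl1, read -0.35 each at 14.7 and 14.6 in knockout. Genes of the respiratory chain (oxidative phosphorylation) had a mean of -0.36 over 30 genes, with Sdhd at -0.50 and Atp5j at -0.37, and 0 passed over the list alone. Sdhd lies between Plet1os and Ppp2r1b on chromosome 9, in the stretch within 20 Mb of Anp32a. Glycolysis genes had a mean of -0.28 over 14 genes, 4 of them lower over the list alone, among them Pgk1 (-0.41) and Tpi1 (-0.61). FoxO targets had a mean of -0.24 over 16 genes, with Klf9 at -0.34 and Bnip3 at -0.45 and none past the list alone. Camera at its preset correlation gave these 4 lists adjusted p = 1.7e-09, 2.9e-09, 0.00456 and 0.011, and each had adjusted p = 0.614 with an estimated correlation. The array means of the muscle list overlapped between the genotypes (exact permutation p = 0.0571, adjusted 0.233 over 38 lists): knockout 2 and knockout 3 lay at -1.08 and -0.54 relative to the mean of all arrays, knockout 1 and knockout 4 at 0.09 and 0.21, and wild types at 0.09 to 0.57. Of these 4 lists only glycolysis had array means that did not overlap (exact permutation p = 0.0286, adjusted 0.181). Leaving out knockout 2 alone gave a muscle mean of -0.41 and a respiratory chain mean of -0.23. Without knockout 2 and 3 the muscle mean was -0.18 and the respiratory chain and FoxO means -0.06 and -0.09, neither of which passed (camera adjusted p = 0.0835 and 0.122). With the muscle mean as a covariate the respiratory chain and FoxO means were 0.0386 and -0.0458 and did not pass (camera adjusted p = 0.327 and 0.369), and with the erythroid mean the FoxO mean was -0.13 (camera adjusted p = 0.155). The glycolysis mean was -0.11 with the muscle covariate and -0.12 without knockout 2 and 3, and kept its call.

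Marrow and bone lists lay higher in the knockout. Cell cycle genes had a mean log2 fold change of 0.52 over 25 genes, all above 0 and 17 of them higher over the list alone, with Rrm2 at 0.85 and Bub1b at 0.49. B cell genes had a mean of 0.49 over 17 genes, all above 0 and 6 higher over the list alone, including the pre-B cell genes Vpreb1 (0.996) and Igll1 (0.76). Osteoclast genes, such as the proton pump subunit gene Tcirg1 (0.53) and the integrin gene Itgb3 (0.67), had a mean of 0.34 over 13 genes, 9 higher and 1 lower over the list alone. Osteoblast and osteocyte genes had a mean of 0.25 over 15 genes, 3 higher over the list alone, among them the osteocyte genes Dmp1 (0.65) and Phex (0.71), and Phex also passed over all genes without knockout 1 (0.87, limma adjusted p = 0.0306). For these 4 lists camera's adjusted p at its preset correlation was 2.9e-09, 2.3e-06, 6.1e-06 and 0.00139, and each had adjusted p = 0.614 with an estimated correlation. The array means of the cell cycle list overlapped between the genotypes, and those of the other 3 did not (exact permutation p = 0.0286 each, adjusted 0.181). The cell cycle mean was 0.26 with the muscle covariate and 0.14 with the erythroid covariate and kept its call, but followed the erythroid list across the 8 arrays (r = 0.963, exact p = 0.000372). The B cell mean was 0.32 without knockout 3, 0.30 with the erythroid covariate and 0.32 without knockout 2 and 3, and the osteoclast mean 0.22 with the muscle covariate, all called. The osteoblast and osteocyte mean was 0.16 without knockout 2 and 3 and passed. With the muscle mean as a covariate the osteoblast and osteocyte mean was 0.13 and no longer passed (camera adjusted p = 0.23).

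Erythroid genes had a mean of 0.65 over 17 genes with wide spread (SD of array means 0.52 in knockout and 0.54 in wild type), with Ermap at 1.07 and Slc4a1 at 0.82 and the most abundant by the mean of all 8 arrays, Car2 and Tfrc, at 0.67 and 0.18 with levels of 13.4 and 13.02 in knockout. Neutrophil genes had a mean of 0.26 over 16 genes, with Mmp9 at 0.40 and Camp at 0.30, and cytosolic ribosome genes 0.10 over 18 genes, with Rpl3 at 0.20 and Rpl8 at 0.17. Adipocyte genes lay lower, at -0.23 over 17 genes, with Slc2a4 at -0.94 and Car3 at -0.24. No member of these 4 lists passed over the list alone. Camera's adjusted p was 0.000603, 0.00622, 0.00527 and 0.0447, against adjusted p = 0.748, 0.807, 0.748 and 0.844 with an estimated correlation. The erythroid mean was 0.41 without wild type 3 and 0.40 with the muscle covariate, called in both, and the neutrophil call was lost without wild type 3, wild type 4 or knockout 3 (0.16, 0.15 and 0.13, camera adjusted p = 0.0855, 0.103 and 0.115). So was the adipocyte call without any 1 of knockout 1, 2 and 3 and wild type 3 and 4 (-0.19, -0.12, -0.14, -0.12 and -0.18, camera adjusted p = 0.112, 0.245, 0.176, 0.323 and 0.0959), while it was -0.45 without knockout 4. With the muscle covariate the ribosome and neutrophil means were 0.0198 and -0.0278 and lost their calls (camera adjusted p = 0.631 and 0.927). Both calls were also lost with the erythroid covariate (0.0665 and -0.0241, camera adjusted p = 0.139 and 0.837) and without knockout 2 and 3 (0.0408 and 0.0403, camera adjusted p = 0.233 and 0.631). The adipocyte mean turned positive in these 3 settings, where it was called higher with the muscle covariate (0.20, camera adjusted p = 0.0484) and the erythroid covariate (0.16, 0.0112) but not without knockout 2 and 3 (0.0627, 0.843), so its direction is not settled. Its call was lost after quantile normalization or median centring (camera adjusted p = 0.0619 and 0.0614).

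**Figure D3:**
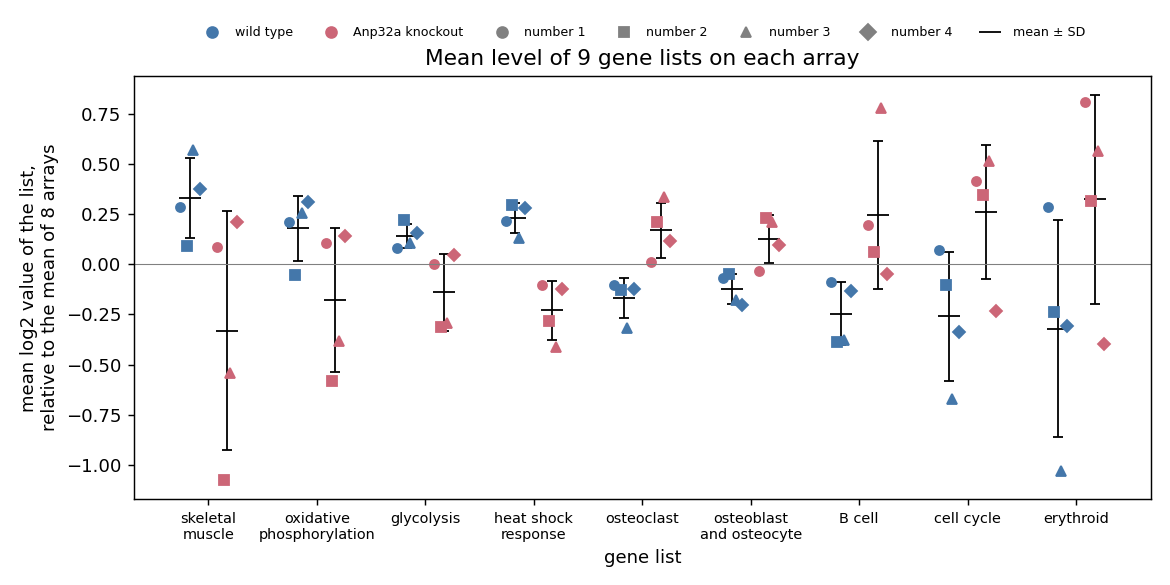
Mean log2 value of 9 gene lists on each array, relative to the mean of the 8 arrays, with the lists along the horizontal axis; marker shape gives the array number and bars are mean ± SD (n = 4 per genotype). Heat shock means lie at -0.10 to -0.41 in knockout and 0.13 to 0.30 in wild type, while knockout 4 lies among the wild types for the muscle, cell cycle and erythroid lists.

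Heat shock genes were lower in the knockout, with groups that did not overlap. The mean log2 fold change was -0.46 over 12 chaperone and co-chaperone genes, with knockout array means of -0.10 to -0.41 and wild-type means of 0.13 to 0.30 (exact permutation p = 0.0286, the smallest possible, adjusted 0.181 over 38 lists). In this the list was 1 of 6, with the autophagy, osteoblast and osteocyte, osteoclast, B cell and glycolysis lists, where chance gives 1.09 on average over splits. Lists can move together, and the number in other splits was not counted, so the 6 do not exclude chance. Over the list alone 6 members were lower, and over all genes 1, Hsph1. Besides Hsph1, which fell in both of its probe sets, the inducible Hsp70 genes Hspa1a (-1.09) and Hspa1b (-0.88) and the small heat shock protein gene Hspb1 (-0.98) were among the 6. The list member Cryab, named outside the rule, read -1.24. It lies between Plet1os and Ppp2r1b on chromosome 9, in the stretch within 20 Mb of Anp32a. Without the genes of that stretch the heat shock list kept its camera call. Camera's adjusted p was 2.7e-05, with adjusted p = 0.491 with an estimated correlation, and fry's adjusted p was 0.0341, the only list to pass that test. Circadian clock genes had a mean of -0.13 over 17 genes, 2 lower over the list alone, Nfil3 (-0.62) and Cry1 (-0.29). Their camera adjusted p was 0.0208, with adjusted p = 0.614 with an estimated correlation, and the call was lost without knockout 2 or knockout 3 (-0.11 and -0.08, camera adjusted p = 0.0639 and 0.11). The circadian mean was -0.00207 with the muscle covariate, -0.0782 with the erythroid covariate and -0.00815 without knockout 2 and 3 (camera adjusted p = 0.976, 0.0723 and 0.895). That call was also lost over all probe sets (-0.0646) and among detected genes (-0.12, camera adjusted p = 0.1 and 0.0649). The osteoclast and neutrophil lists share 1 gene, Mmp9, and the muscle list shares 0 with the respiratory chain, glycolysis and heat shock lists.

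The antioxidant enzyme, NRF2 target and chondrocyte lists had means near 0, while the DNA damage list lay higher by its mean. By the median log2 fold change the NRF2 targets (0.21) lay above the DNA damage genes (0.11). Both lists had exact permutation p = 0.0857, so the contrast between these 2 rests on the mean and on camera. The reactive oxygen production list had a mean of 0.14 over 9 genes and did not pass (camera adjusted p = 0.443). DNA damage response genes had a mean log2 fold change of 0.18 over 17 genes, 14 of them above 0, with 0 past the list alone. H2afx, the gene of histone H2AX, read 0.68 and Nbn -0.20 (camera adjusted p = 0.0112 for the list, with adjusted p = 0.614 with an estimated correlation). The DNA damage call was lost with the mean of all probe sets (0.0862, camera adjusted p = 0.0885), over all probe sets (0.0792, 0.06), with the muscle covariate (0.0773, 0.4), with the erythroid covariate (0.0728, 0.195) and without knockout 2 and 3 (0.11, 0.19). Antioxidant enzymes had a mean of 0.01 over 21 genes, where camera's direction was down (adjusted p = 0.954), with Gpx1 at 0.37 and Txnrd1 at -0.14 and 0 past the list alone. Over all genes, H2afx and Gpx1 passed without knockout 4 (0.86 and 0.46, limma adjusted p = 0.0275 and 0.039). Among 19 NRF2 targets, with a mean of 0.07 (camera adjusted p = 0.582), 1 was higher over the list alone, the transketolase gene Tkt (0.46), and Pgd of the same pentose phosphate pathway read 0.33. Chondrocyte genes had a mean of 0.03 over 25 genes (camera adjusted p = 0.753), with Matn1 at 0.68 and Cilp at -0.53 and 0 past the list alone. Cilp is a gene within 10 Mb of Anp32a. Camera called 15 of the 38 lists, 8 higher and 7 lower, and 0 with an estimated correlation (1 at unadjusted p under 0.05). Fry called 1, and the exact permutation test of array means 0 (6 at unadjusted p under 0.05). That 0 decides little, since the smallest possible exact permutation p is 0.0286 before adjustment over 38 lists.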

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

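Tests chosen after their result was seen were that of position-independent action for the calls near Anp32a, that of a gain of all other cell types for the muscle lists and that of handling for the heat shock list, and the window of 20 Mb for called probe sets. That the split counts should also bear on the reading of parting probe sets and of odds ratios was settled after they were seen, and the splits with covariates were added after the data were seen. Knockout 4 was singled out because leaving it out moved the count most.

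Of 220 groups of 4 arrays examined, 11 held an array whose gap to its nearest neighbour, as a share of the group's range, lay above Dixon's 95% critical value, and chance gives 11. Wild type 4 was apart for Slc4a4 (7.88), Nbn (8.84), Tcirg1 (9.89) and Cry1 (7.91). Wild type 1 stood apart for Dapk2 (9.54), wild type 2 for Pgk1 (13.6) and wild type 3 for the osteoclast list (-0.32 relative to the mean of all arrays). Knockout 3 stood apart for the brighter Atm probe set (8.53), and for Igll1 (9.62), and knockout 2 for Plet1os (3.74) and the hypertrophic chondrocyte list (0.23). Outside the named genes, 6 called probe sets have no gene symbol, so they enter no gene-level count.

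The first pattern is the crowding of called probe sets near Anp32a: among the 14 placed probe sets of smallest p, 11 lay within 20 Mb. Of 35 splits of the 8 arrays into 4 and 4, 1 did so, the real one, with at most 2 in any other. The window and the number 14 were taken from the real comparison, and the 11 include the targeted gene itself. The splits therefore set the real division apart but do not by themselves exclude chance. An action of lost Anp32a on genes without regard to position is argued against by that crowding for the called probe sets as a group, not for any single gene. The odds ratio within 10 Mb decides nothing, with or without Anp32a (1.47 and 1.45), since 5 of 35 splits gave 1.47 or more (highest other 2.75). Differences in muscle or erythroid content as the whole cause are argued against by the crowding left with both means as covariates, 10 of 14, which 1 of 35 splits so fitted gave, the real one (highest other 2), whereas the odds ratio of 1.83 again decides nothing (4 of 35 splits, highest other 2.54), and other cell types were not tested. A chromosome segment of another strain around the altered gene, whose variants might weaken hybridisation to single probe sets, remains a hypothesis. Probe sets of a gene parted by 0.5 log2 or more in 14 of 100 genes within 10 Mb against 425 of 9026 elsewhere (odds ratio 3.29, Fisher's exact p = 0.000286, leaving out 5 genes already seen to part). Of 35 splits, 13 gave an odds ratio as high (highest other 8.42). The splits cannot decide the question, since some keep 3 of 4 arrays of each genotype together and so carry part of the genotype difference. The split of 8.42, wild type 1 with knockouts 1, 2 and 4, is 1 of them, so no conclusion is drawn from the parting. A true local effect of the altered gene on its neighbours, Atm included, was not tested and stays open. So does an action on any single neighbour without regard to position.

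The second pattern is the lower muscle and respiratory chain lists. With the muscle mean as a covariate the respiratory chain mean went from -0.36 (SE 0.197) to 0.0386 (SE 0.0799), which is consistent with less muscle on knockout 2 and knockout 3, and the 2 lists followed each other across 8 arrays (r = 0.973, exact p = 0.000298, rho = 0.952, exact p = 0.00114; r = 0.789 without the 2 arrays farthest in muscle; adjusted p of r = 0.000744 over 4 relations). A uniform gain of all other cell types was not decided: erythroid, B cell and osteoclast means lay at 0.65, 0.49 and 0.34 and endothelial and tendon means at -0.10 and -0.15, while the lowest, adipocyte, lay at -0.23 with SE 0.270. The most abundant muscle genes read 14.6 and 14.7 in knockout, and a change of muscle itself in the knockout was not tested.

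The third pattern is the heat shock list. Less muscle is argued against as its cause, since the mean stayed at -0.37 (SE 0.103) with the muscle covariate, from -0.46 (SE 0.0818). Handling before lysis remains open, as no handling time is given; immediate early genes had a mean of 0.09, opposite in sign, and did not pass (exact permutation p = 0.171). Loss of Anp32a also remains open as a hypothesis.

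Whether chance can be excluded was tested over 35 splits. The 11 genes were not beyond it, since 2 of 35 splits gave as many: the split of wild type 1 and knockouts 1, 2 and 3 against the rest gave 434 genes, which points to a structure of the samples. That split keeps 3 of 4 arrays of each genotype together, the same division without knockout 4 gave 0 genes, and what the structure is was not tested. For probe sets 2 of 35 gave 24 or more (highest other 640), and for lists 11 of 35 gave 15 or more (highest other 19), so neither count excludes chance. Without knockout 4, 1 of 35 splits of the 7 arrays into 3 and 4 gave 1786 genes, the real one, and every other gave 0. That sets the real division apart for those 7 arrays, but the array left out was chosen for its effect on the count.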

How the results depend on the processing

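Leaving out knockout 2 and 3 together, leaving out genes within 20 Mb of Anp32a, a detection filter, the exact permutation of list means, the joint covariates, alone and over splits of the arrays, and the estimated correlation without knockout 4 were chosen after seeing the data. The counts of genes depended on most settings, while the loss of Anp32a in 1 probe set and the fall of the Ppcdc probe set passed under every setting that tested them. Among the settings that tested them, the calls of the dimmer Atm and Pclaf probe sets were lost only under the ordinary per-gene test (adjusted p = 0.172 each, against 0.000938 and 0.000991). Leaving out genes within 20 Mb left all of these probe sets untested, and the filter on median level left out those of Ppcdc and Pclaf. Where no cause is named below, the cause was not tested.

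Leaving out 1 array gave 1 to 1786 genes (0 to 944 higher, 1 to 842 lower), 9 to 3579 probe sets, 13 to 18 lists, an odds ratio near Anp32a of 1.37 to 1.57 (weaker without knockout 1, 1.38, knockout 2, 1.37, or wild type 3, 1.45) and -0.54 to -0.46 for Anp32a at gene level, which passed without knockout 4 (-0.51).

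Genes above the median level gave 7 genes (3 higher), with fewer genes tested. The mean of a gene's probe sets gave 8 lower genes and -2.08 for Anp32a, which then includes its lost probe set, and all probe sets one by one gave 24 calls, 15 of them lower. Anp32a at gene level passed after quantile normalization (-0.50) and with array weights (-0.52), which gave 41 probe sets. The ordinary per-gene test called 0 genes (0 higher, 0 lower; 3372 at an unadjusted p under 0.05, where limma called 11) and 2 probe sets. At adjusted p under 0.1 there were 21 genes, 12 lower, and 73 probe sets. The muscle covariate left 1 gene (0 higher, 1 lower) and 6 probe sets, and the erythroid covariate 5 genes (1 higher) and 11 probe sets. Without knockout 2 and 3 there were 1 gene (0 higher, 1 lower) and 7 probe sets, and without the genes near Anp32a 4 genes (3 higher, 1 lower) and 9 probe sets. Of 38 lists, 0 passed with an estimated correlation, 0 so without knockout 4, 1 by fry and 0 by exact permutation, against 15. The exact permutation test could hardly pass after adjustment, its smallest possible p being 0.0286.

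The numbers 1 to 4 in the titles were also fitted as a block: 4 genes passed (1 higher, 3 lower; 3 of the 11). Wild type and knockout arrays of 1 number correlated at 0.0652, 0.511, -0.339 and 0.303 after group means were removed. The best partner was the knockout of the same number for wild types 2 and 4 only, so whether the numbers pair the samples is not settled.

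Directions reversed as follows. With the mean of probe sets Ppcdc was -0.71, called, and the Anp32 family list -0.15; with all probe sets the latter was -0.23, antioxidant -0.0058 and hypertrophic chondrocyte -0.0496. With the muscle covariate Atm at gene level was 0.00257, Anp32 family -0.0292, p53 0.00342, Wnt -0.0312, chondrocyte -0.12, hypertrophic chondrocyte -0.11, matrix degrading -0.0468, neutrophil -0.0278, macrophage -0.0381, megakaryocyte -0.13, adipocyte 0.20, called, endothelial 0.0664, inflammatory -0.0114 and respiratory chain 0.0386. With the erythroid covariate Atm was 0.0174, Tfrc -0.0197, Anp32 family -0.0167, antioxidant -0.00593, TGF-beta 0.0151, neutrophil -0.0241, megakaryocyte -0.35 and adipocyte 0.16, both called, endothelial 0.0338, tendon 0.0222, synovial fibroblast 0.0817 and interferon -0.0215. The list used as covariate was not tested, since the covariate fixes it near 0. Without knockout 2 and 3 Atm was 0.00945, Anp32 family -0.00816, hypertrophic chondrocyte -0.0263, matrix degrading -0.0375, macrophage -0.0387, megakaryocyte -0.00552 and adipocyte 0.0627.

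Leaving out 1 array changed the sign of Atm at gene level (-0.0277 to 0.0120) and of lists that did not pass. Their ranges were -0.0817 to 0.0245 for TGF-beta, -0.0769 to 0.129 for chondrocyte, -0.0411 to 0.0790 for hypertrophic chondrocyte, -0.00438 to 0.429 for megakaryocyte and -0.0934 to 0.00669 for synovial fibroblast. For interferon the range was -0.00816 to 0.120, for unfolded protein -0.103 to 0.0034 and for sex-linked -0.0151 to 0.0332.

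Over all settings, named genes kept direction and side of the threshold in 1294 cases, were weaker in 82, stronger in 45 and reversed in 7. For lists the counts were 715, 46, 24 and 45. Of 67 named genes only 8 were called in the plain comparison, and a gene that stayed uncalled counts as kept. Only a called gene can turn weaker, so all 82 weaker cases are of those 8. In the same way the 46 for lists are of the 15 called lists. These counts therefore do not measure how stable the calls were. The values of the authors' other table were not run, being identical, nor lists under the ordinary per-gene test. On arrays, signal near background limits the probe sets called absent.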

Other observations

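Other gene groups showed single members past the list alone, named here after their values were seen. Among 16 p53 targets, whose mean was -0.05 and median 0.07, the receptor gene Eda2r (log2 fold change -1.08) and the cyclin gene Ccng1 (-0.77) were lower over the list alone. Among 26 Wnt pathway genes, with a mean of 0.08, the Wnt inhibitor genes Sost (0.68), Dkk1 (0.61) and Rnf43 (0.37) were higher and the ligand gene Wnt16 (-0.44) lower over the list alone. Sost is also a member of the osteoblast and osteocyte list. Rnf43 read 4.81 ± 0.14 in knockout and 4.44 ± 0.10 in wild type, a level like that of the absent Mid1 probe sets. None of these p53 and Wnt genes passed over all genes, but without knockout 4 Eda2r, Ccng1, Rnf43 and Wnt16 did (-1.21, -0.92, 0.43 and -0.39, limma adjusted p = 0.026, 0.0297, 0.0297 and 0.0474). The 2 lists did not shift (camera adjusted p = 0.954 and 0.336), though the Wnt list passed with the erythroid covariate (0.14, camera adjusted p = 0.0216). The relatives Anp32e and Anp32b read 0.47 and 0.27, with limma adjusted p = 0.178 and 0.225 over all genes and 0.0496 and 0.0853 over the list alone. That list includes the targeted Anp32a, which takes the first rank in its adjustment, so the value of Anp32e under 0.05 rests on it. Past the list alone were also 1 higher member each of the macrophage, T and NK cell, inflammatory and immediate early lists, 1 lower each of the synovial fibroblast and interferon lists, 1 higher and 3 lower of the hypoxia list and 3 lower of the unfolded protein list, none of them over all genes.

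The remaining lists did not pass camera (adjusted p from 0.0603 to 0.954). Mean log2 fold changes were 0.07 for the Anp32 family, 0.14 for reactive oxygen production, -0.05 for autophagy, -0.03 for TGF-beta and BMP signalling, 0.03 for hypertrophic chondrocyte and 0.05 for matrix degrading enzymes. They were 0.15 for T and NK cell, 0.08 for macrophage and monocyte, 0.19 for megakaryocyte and platelet, -0.10 for endothelial, -0.15 for tendon and -0.05 for synovial fibroblast genes. They were 0.07 for interferon response, 0.08 for inflammatory mediators, 0.09 for immediate early genes, -0.13 for hypoxia, -0.05 for the unfolded protein response and 0.01 for sex-linked genes. The median had the opposite sign to the mean for the p53, macrophage, TGF-beta and synovial fibroblast lists, and camera's direction for the sex-linked and antioxidant lists. Leaving out 1 array brought some past camera's threshold: endothelial without wild type 2, knockout 3 or knockout 4 (-0.16, -0.13 and -0.16), tendon without wild type 2 or knockout 2 (-0.20 each), hypoxia without knockout 2 (-0.16), megakaryocyte without knockout 4 (0.429), and immediate early genes without wild type 2 or knockout 3 (0.12 each). With an estimated correlation the endothelial and megakaryocyte lists did not pass without knockout 4 (camera adjusted p = 0.746 and 0.673). With the muscle covariate TGF-beta (-0.10), tendon (-0.14), immediate early (0.11), hypoxia (-0.14) and unfolded protein (-0.18) lists passed. With the erythroid covariate immediate early genes passed (0.12), and megakaryocyte genes were called lower (-0.35, camera adjusted p = 3.7e-10), opposite to their mean of 0.19 and to the call without knockout 4, so their direction is not settled. Without knockout 2 and 3 the tendon (-0.16), immediate early (0.14), hypoxia (-0.10) and unfolded protein (-0.14) lists passed. The endothelial list passed with the replicate block (-0.10) and, over all probe sets one by one, so did endothelial (-0.09), tendon and hypoxia (-0.11 each). The X-inactivation gene Xist read 3.89 in knockout and 3.98 in wild type, and the Y-linked gene Ddx3y 11.3 in both.

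Across the 8 arrays the erythroid and cell cycle lists followed each other (r = 0.963, exact p = 0.000372, rho = 0.952, exact p = 0.00114; r = 0.945 without the 2 arrays farthest in erythroid genes; adjusted p of r = 0.000744 over 4 relations). Muscle and heat shock means gave r = 0.748 (exact p = 0.0243, rho = 0.619, exact p = 0.115), and r = 0.273 without the 2 arrays farthest in muscle, so that relation rests on those arrays (adjusted p of r = 0.0324). Within the genotypes its sign differed, with r = 0.725 in knockout and -0.822 in wild type, 4 arrays each and too few to test. Muscle and erythroid means gave r = -0.571 (exact p = 0.144, rho = -0.786, exact p = 0.0279; r = -0.721 without the 2 arrays farthest in muscle; adjusted p of r = 0.144).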
